A study of Mus musculus with 6 samples.

How the data were processed

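RNA of BV2 cells, an immortalized mouse microglial line, was measured by RNA sequencing in 6 libraries. The labels put 3 libraries in a group named shscr-ctr and 3 in a group named shNumb-ctr. Cells were lysed in TRIzol and the RNA was sequenced by a company, per the labels' protocols. The labels do not say that the 3 samples of a group were separate cultures, so the p-values given here measure only the spread between these samples, which may be technical. No label names a sequencing batch or date, so batches could not be compared.

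The authors deposited, for each library, a value for each of 22672 listed genes, in the same order in all 6 libraries. The column headers name no unit. The deposited values are fractional and never negative, and they sum to between 451077 and 455561 per library, so they were read as FPKM (fragments per kilobase of transcript, scaled to sequencing depth). TPM cannot be excluded as the unit, and either would be a value normalized by the authors for gene length and for library depth. The authors named CASAVA and DESeq2 in their processing notes, with no version and no role. Of the listed genes, 556 carry names of the form given by default to assembled transcripts by StringTie, per the gene names in the deposited files. The aligner, the genome build and the annotation are not given in the sources used here. Read counts were not used here and the depth behind each value is unknown, so no counting interval or detection limit is given. A value of 0 is reported only as listed at 0.

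Values were analysed as log2(value + 1), a pseudocount of 1. Fold changes called log2 are on that scale, which understates the change of genes with low values, and folds of group means are given beside them. Genes with a value of at least 1 in at least 3 libraries were tested, which left 10594 genes, 182 of them assembled transcripts. Another 7522 of the listed genes were at 0 in all 6 libraries. The libraries labelled shNumb-ctr were compared with those labelled shscr-ctr in limma (version 3.58.1, R version 4.3.3) with a mean-dependent prior variance (limma-trend), no covariate, a two-sided test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The plan named a count-based test first and this limma fit for the case that the deposited values were not counts, which is the case that applied.

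Before the data were examined, 46 gene lists were fixed: pathways, complexes and cell states of microglia, and markers of other cell types. The 38 lists with at least 5 tested members were tested in camera with a preset correlation between genes of 0.01, adjusted over the 38 lists. The test was repeated with a correlation estimated for each list, and in fry, which asks whether the genes of a list move on balance in 1 direction. For each list the members past the threshold are counted over all tested genes and again adjusted over the list alone. A further 8 lists were chosen after the values had been seen, and are reported only in the closing section.

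The genes named in the text were chosen by a rule fixed with the lists: Numb, Numbl and Ifi204; 12 genes of microglial activation and Notch signalling, whatever their value; the 8 called genes with the largest fold change in each direction among those with a mean of at least 5 and no overlap between the groups, without predicted genes and pseudogenes; and, from each list, at most 2 called members per direction with the smallest adjusted p. Where no member of a list was called, that rule allowed at most 1 member, that with the smallest p, such as Aldoc. Genes named outside that rule, among them all members behind a list count of 5 or fewer, were chosen after their values were seen. They are Trem2, Gpnmb, Lpl, Mmp9, Acod1, Lcn2, Gm49380 and Gm49378 in the report, the genes of the closing section, and those members of small list counts.

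Transcript sequence shared between genes was measured with GENCODE mouse release M21 (GRCm38), used for sequence and chromosome only because the authors' build is not known. For each gene, windows of 50 bases, taken every 10 bases along its longest transcript, were looked up in the transcripts of all other genes (Python 3.11.15). Of the tested genes, 98.1% had such a value. Genes with over 20% of their windows shared are called uncertain here, because reads of a near-identical copy could have been assigned to them; 215 of the called genes were in that class.

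The fit was tested on simulated data for the comparison of the 2 groups, with 200 of 10594 genes changed. It recovered 52.2% of genes changed by 0.3 (log2), 86.6% of those changed by 0.6 and 97% of those changed by 1, with 5 false calls among 162 and the right sign in 100% of the recovered genes. With no gene changed, 0 genes and 0 of 38 lists were called. The simulated genes varied independently of each other. That run therefore does not show how often camera calls lists whose genes are correlated.

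The alternatives fixed before the data were examined and run here were pseudocounts of 0.1 and 5, no filter on low values, values of at least 5 in at least 3 libraries, a fold change of at least 1.5, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. The stricter filter had been planned in CPM and was applied to the deposited unit. The other alternatives fixed then, which need counts (2 other count-based tests, voom, and 2 other scalings of counts), were not run. Added after the data were seen were median-of-ratios rescaling, quantile normalization, a correction for GC content and transcript length, a constant prior variance, leaving out genes with over 20% shared windows, and every list without shNumb-ctr replicate 2.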

Results

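The series compared BV2 microglial cells carrying a hairpin labelled shscr, by the usual reading a scrambled control, with cells carrying a hairpin labelled shNumb. Its title sets Numb and the interferon-inducible gene Ifi204 beside microglial activation and inflammation after lipopolysaccharide. There were 3 libraries per group. No label names a treatment, and the suffix ctr is not spelled out. The deposited FPKM values summed to between 451077 and 455561 per library, and between 13513 and 13823 genes were above 0. Mitochondrially encoded genes made up 5.93% to 6.48% of the sum. Correlations of log2 values were 0.993 to 0.995 between libraries of a group and 0.990 to 0.992 between groups. The sequencing depth is unknown.

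Numb, the adaptor protein that antagonizes Notch receptors and the gene the hairpin is named for, was not lower in the libraries labelled shNumb-ctr. Numb (ENSMUSG00000021224, chromosome 12 in GENCODE release M21) was at 35.8, 36.7 and 36.1 FPKM in shscr-ctr replicates 1, 2 and 3, a mean of 36.2 ± 0.455 (SD, n = 3). It was at 38.0, 37.2 and 40.0 FPKM in shNumb-ctr replicates 1, 2 and 3, a mean of 38.4 ± 1.44 (SD, n = 3). The fold of means was 1.06 and the log2 fold change 0.08, with an SE of 0.036 and a 95% interval of 0.001 to 0.17, and it did not pass the threshold (limma adjusted p = 0.137). The target gene therefore goes against its label, and each direction given here is that of the libraries labelled shNumb-ctr against those labelled shscr-ctr. Its paralog Numbl (chromosome 7) was 1.33-fold higher in the libraries labelled shNumb-ctr, 5.32 ± 0.522 against 4.01 ± 0.124 FPKM (SD, n = 3, log2 0.33, SE 0.071, limma adjusted p = 0.0170). The call for Numbl was lost without shscr-ctr replicate 3, shNumb-ctr replicate 1 or shNumb-ctr replicate 3, with limma adjusted p of 0.0538, 0.0557 and 0.0566.

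Ifi204 (ENSMUSG00000073489, chromosome 1), a DNA-binding protein of the HIN-200 family, was slightly higher in the libraries labelled shNumb-ctr, at 15.02 ± 0.861 against 12.96 ± 0.168 FPKM (SD, n = 3). The fold was 1.16, with all 3 shNumb-ctr libraries above all 3 shscr-ctr libraries (SE 0.048, limma adjusted p = 0.0269), and the Ifi204 log2 fold change was 0.20. The call was lost when any library but shNumb-ctr replicate 3 was left out, with limma adjusted p of 0.0754, 0.0542 and 0.0776 without shscr-ctr replicates 1, 2 and 3, and 0.0869 and 0.0714 without shNumb-ctr replicates 1 and 2. Of its transcript windows, 30.7% also occur in other genes, so its level is uncertain.

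**Figure D1:**
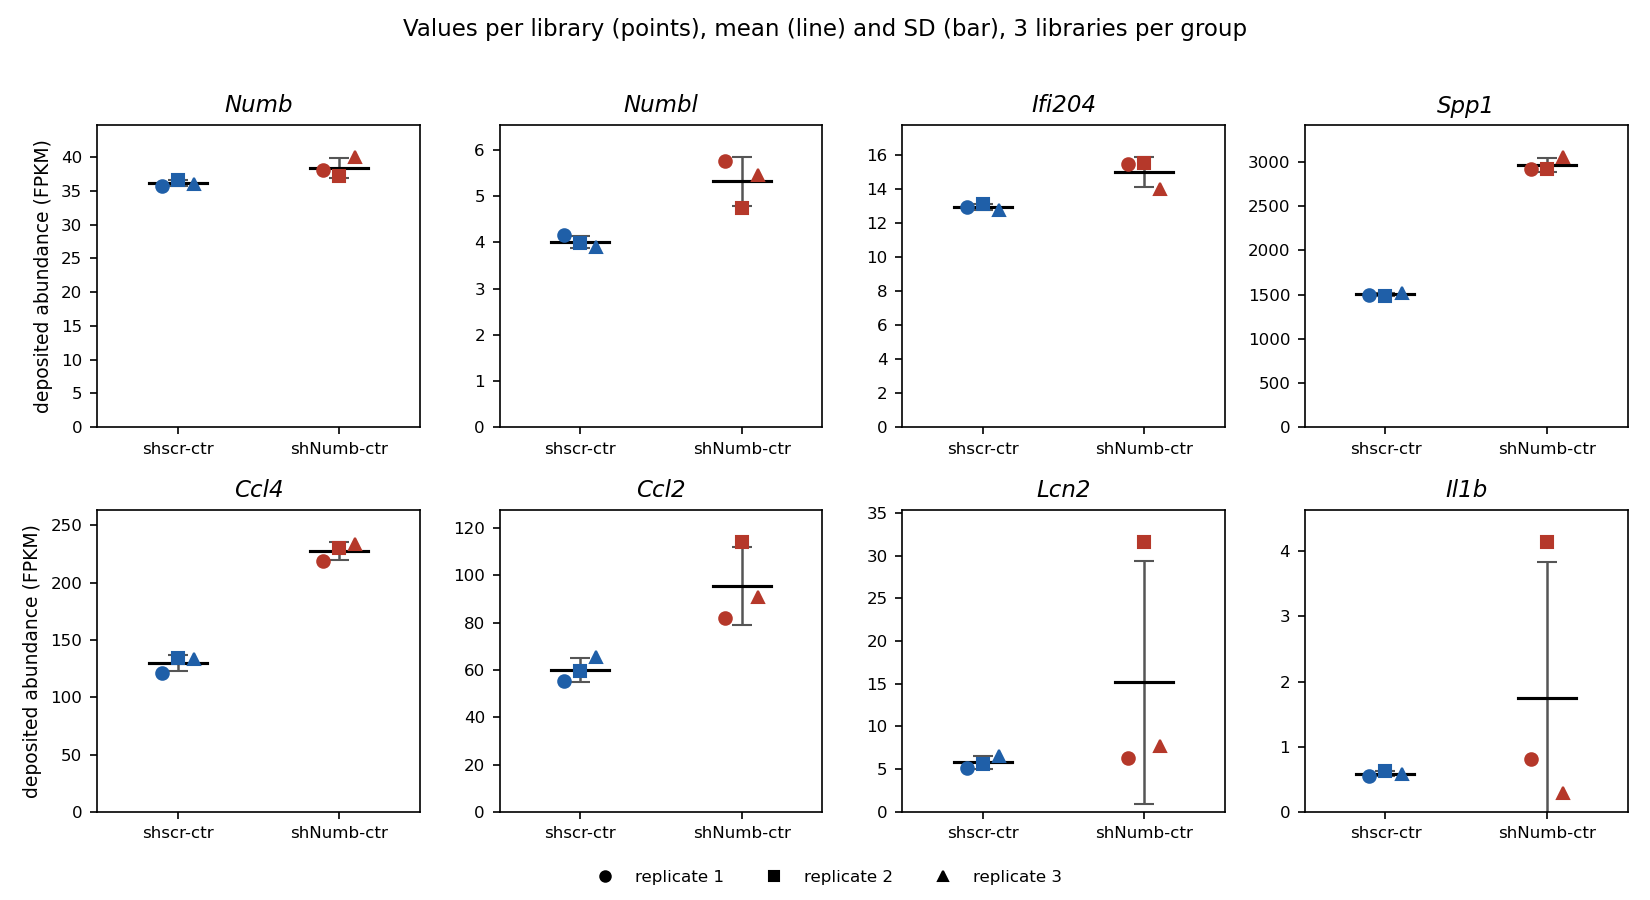
Deposited abundance (vertical axes, FPKM, starting at 0) of 8 genes in each library, with blue points for shscr-ctr, red points for shNumb-ctr, a line at the group mean and a bar of 1 SD (n = 3; the lower end for Il1b runs below 0 and is not drawn). Numb lies at 35.8 to 36.7 in shscr-ctr and 37.2 to 40.0 in shNumb-ctr, the groups of Spp1 and Ccl4 lie far apart, and the high mean of Lcn2 and Il1b in shNumb-ctr comes from replicate 2.

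Between the labels, the libraries differed in many genes by small amounts. In the libraries labelled shNumb-ctr, Spp1, Plau and the chemokine genes Ccl4, Ccl3 and Ccl5 rose, the lists of chemokines and lysosomal genes were called upward in camera, and those of mitosis and DNA replication downward. None of these list calls held with an estimated correlation between genes, where their adjusted p were 0.198, 0.178, 0.269 and 0.269. Of 10594 genes tested, 1989 passed the threshold (18.8%), 859 higher and 1130 lower in the libraries labelled shNumb-ctr, with a median absolute log2 fold change of 0.21 (limma, adjusted p under 0.05). On the log2(value + 1) scale, at least 1.5-fold changes were found for 53 higher and 14 lower genes, and at least 2-fold changes for 7 and 2. Both of the latter, Gm49380 and Gm49378, were predicted genes with 83.6% and 98.1% shared windows, and uncertain. They were chosen after their values were seen. The split depends on scaling: after median-of-ratios rescaling, 1057 genes were higher and 812 lower, a share of 56.6% higher against 43.2% as deposited. Without shscr-ctr replicate 1, shscr-ctr replicate 3, shNumb-ctr replicate 1 or shNumb-ctr replicate 3, the higher genes numbered 499, 569, 515 and 543, and the lower genes 465, 630, 623 and 608. The groups did not overlap in 39.9% of tested genes, where chance gives 10%.

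Spp1, the secreted glycoprotein osteopontin, rose from 1502 ± 19.3 to 2963 ± 76.6 FPKM in the libraries labelled shNumb-ctr (SD, n = 3), 1.97-fold (log2 0.98, SE 0.028, limma adjusted p = 4.0e-06). Plau, the urokinase plasminogen activator, rose 2.00-fold from 83.4 ± 3.86 to 166 ± 12.4 FPKM (log2 0.99, SE 0.057, limma adjusted p = 1.4e-04). Among called genes with a mean of at least 5 FPKM and no overlap between the groups, predicted genes left out, the other large rises were those of Dok7 (2.19-fold), Ccl5 (2.12-fold), Lat (1.82-fold), Bex3 (1.77-fold), Ccl4 (1.75-fold) and Atp6v0d2, a subunit of the vacuolar proton pump (1.75-fold). The largest falls under the same limits were those of Fos, an immediate early transcription factor, from 31.5 ± 5.51 to 18.1 ± 3.85 FPKM (SD, n = 3, log2 -0.77, SE 0.153, limma adjusted p = 0.0136), and of Rpl17, from 301 ± 30.3 to 180 ± 37.3 (log2 -0.76, SE 0.139, limma adjusted p = 0.0104). With 44.5% of its windows shared, Rpl17 is uncertain. Ighm, the immunoglobulin mu heavy chain, fell from 32.4 ± 1.88 to 19.4 ± 0.682 FPKM, and Cebpa, a transcription factor of the myeloid lineage, from 6.44 ± 0.341 to 3.98 ± 0.217 (SD, n = 3, log2 -0.71 and -0.58, limma adjusted p = 2.6e-04 and 0.0013). Fam167b, Ctsh, Rufy4 and Mcemp1, with log2 fold changes of -0.62, -0.61, -0.54 and -0.54, completed the falls named by the rule.

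**Figure D2:**
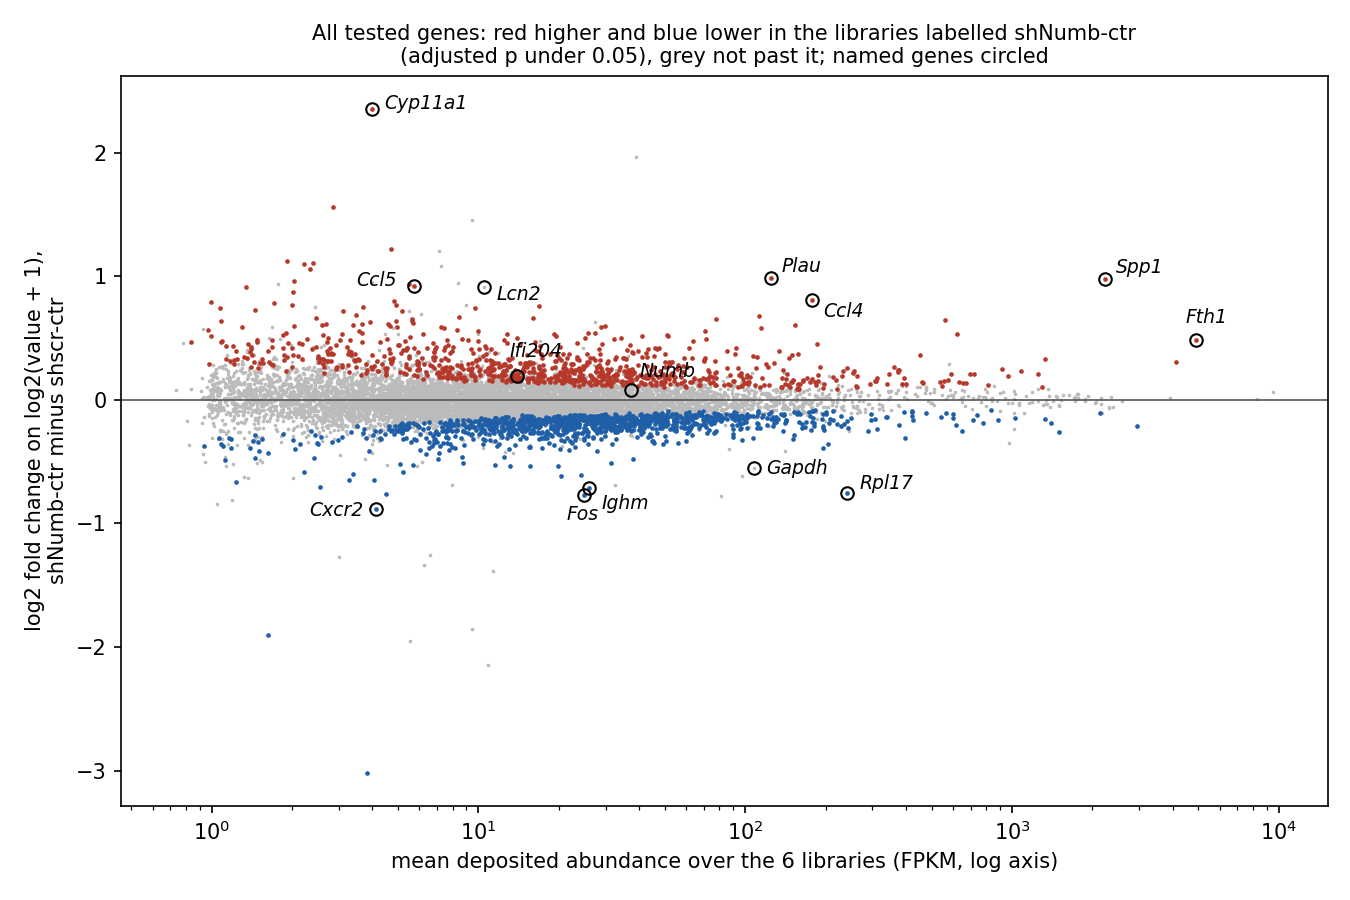
Each point is 1 of the 10594 tested genes, placed by its mean deposited abundance over the 6 libraries (horizontal log axis, FPKM) and its log2 fold change between the libraries labelled shNumb-ctr and shscr-ctr (vertical axis); red and blue points passed the threshold. Most called genes lie close to 0, with a median absolute log2 fold change of 0.21, and Spp1 (0.98) and Plau (0.99) stand out among abundant genes.

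Genes of the disease-associated microglial state, described for microglia around plaques and damaged neurons, rose together: 18 of 28 members were higher and 0 lower in the libraries labelled shNumb-ctr (19 and 0 adjusted over the list alone). Their median log2 fold change was 0.21 (camera adjusted p = 1.3e-14, and adjusted p = 0.178 with an estimated correlation). Beside Spp1 they included Csf1, a growth factor of microglia, from 42.2 ± 1.57 to 60.6 ± 0.578 FPKM (SD, n = 3, log2 0.51, SE 0.034, limma adjusted p = 2.6e-04). Trem2, the lipid-sensing receptor of that state, rose 1.203-fold, Gpnmb 1.26-fold and Lpl, lipoprotein lipase, 1.37-fold. Lysosomal genes moved in the same direction, with 21 of 40 higher and 2 lower (24 and 4 adjusted over the list alone, camera adjusted p = 4.0e-09, and adjusted p = 0.178 with an estimated correlation). The protease gene Ctsb rose from 396 ± 4.63 to 509 ± 10.4 FPKM (SD, n = 3, log2 0.36, SE 0.025, limma adjusted p = 2.9e-04) and Atp6v0d2 from 12.2 ± 0.225 to 21.4 ± 0.818. The exceptions were Ctsh, which fell from 29.4 ± 0.909 to 19.0 ± 1.13 FPKM (log2 -0.61), and Ctsc (log2 -0.12), whose call was lost in 9 of 16 alternatives with limma adjusted p up to 0.102.

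Among receptors of phagocytosis, 8 of 22 were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 6.3e-05, and adjusted p = 0.269 with an estimated correlation). Mfge8, which bridges apoptotic cells to phagocytes, rose 1.29-fold to 169 ± 6.66 FPKM (SD, n = 3, log2 0.37), and Itgam 1.15-fold, although 72.2% of its windows are shared and its level is uncertain. Of 9 complement genes, C3, Itgam, Itgax, C1ra and C3ar1 rose and C4b fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0015, and adjusted p = 0.178 with an estimated correlation). C3 rose from 18.9 ± 0.329 to 23.4 ± 0.494 FPKM (SD, n = 3, log2 0.30, SE 0.035, limma adjusted p = 0.0021). C1ra and C4b are uncertain at 51.0% and 35.5% shared windows. Without shNumb-ctr replicate 2, 3 complement genes were higher and 1 lower. The calls for C1ra, C3ar1 and C4b were lost in 4, 7 and 2 alternatives, with limma adjusted p up to 0.0784, 0.120 and 0.0585.

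Chemokine genes had the highest median change of the 38 lists tested: 5 of 9 were higher and 0 lower in the libraries labelled shNumb-ctr (6 and 0 adjusted over the list alone), with a median log2 fold change of 0.65 (camera adjusted p = 2.8e-05, and adjusted p = 0.198 with an estimated correlation). Ccl4 rose from 130 ± 7.11 to 227 ± 7.78 FPKM, Ccl3 from 437 ± 19.1 to 686 ± 46.8, Ccl2 from 60.0 ± 5.09 to 95.5 ± 16.6 and Ccl5 from 3.68 ± 1.03 to 7.80 ± 1.58 (SD, n = 3), with log2 fold changes of 0.81, 0.65, 0.65 and 0.92. Their limma adjusted p were 1.1e-04, 5.1e-04, 0.0081 and 0.0117, and Ccl9 was the remaining riser (log2 0.25). Cxcl10 was at 3.48 ± 2.68 against 1.40 ± 0.228 FPKM and did not pass (log2 0.75, limma adjusted p = 0.151). Of 18 genes for inflammatory cytokines and mediators, 8 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 1.8e-06, and adjusted p = 0.178 with an estimated correlation). They included Ptges, a prostaglandin E synthase, from 1.41 ± 0.0966 to 2.65 ± 0.252 FPKM (SD, n = 3, log2 0.60, SE 0.077, limma adjusted p = 0.0030), Mmp9 (1.69-fold) and Acod1, which makes itaconate (1.48-fold).

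Of the genes fixed for activation, Ccl2 and Ccl5 passed the threshold, and Cxcl10, Tnf, Nos2, Ptgs2, Aif1 and Tlr4 did not. Tnf was at 32.7 ± 6.95 against 32.8 ± 1.75 FPKM (SD, n = 3, log2 -0.03, SE 0.135, limma adjusted p = 0.912). Nos2 was at 24.9 ± 0.627 against 23.5 ± 1.24 (log2 0.08, limma adjusted p = 0.229), and Ptgs2 at 8.63 ± 1.68 against 7.79 ± 0.336 (log2 0.12, limma adjusted p = 0.482). Aif1 was at 4.33 ± 0.650 against 3.60 ± 0.150 (log2 0.21, limma adjusted p = 0.135) and the lipopolysaccharide receptor Tlr4 at 9.32 ± 0.766 against 9.80 ± 0.615 (log2 -0.07, limma adjusted p = 0.524). Il1b and Il6 were below the filter and were not tested. The list of TLR4 and NF-kB signalling was not called, with Irak2 and Tnip1 higher and Ticam2, Myd88, Traf6 and Tab2 lower of 32 (2 and 4 adjusted over the list alone, camera adjusted p = 0.547, and adjusted p = 0.770 with an estimated correlation). The calls for Tnip1, Ticam2, Myd88, Traf6 and Tab2 were lost in 7, 7, 9, 7 and 10 of 16 alternatives. In these lists shNumb-ctr replicate 2 stood apart: Il1b was at 4.14 FPKM there and at most 0.810 in the other 5 libraries. Il6 was at 2.84 against at most 0.337, Cxcl10 at 6.56 against at most 2.16, and Lcn2 at 31.6 against at most 7.69. Without that library 3 of the TLR4 and NF-kB genes were higher and 2 lower. Without it 5 of the chemokine genes and 6 of the mediators were higher and 0 lower, with camera adjusted p of 2.2e-05 for both lists, and the sign of Ptgs2 changed to a log2 fold change of -0.019. Tnf, too, changed sign, to 0.0079 without shscr-ctr replicate 3 and 0.15 without shNumb-ctr replicate 1.

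Besides Ifi204, the HIN-200 genes Aim2 and Ifi207 rose, and 0 of the 6 tested fell (5 and 0 adjusted over the list alone, camera adjusted p = 7.8e-04, and adjusted p = 0.178 with an estimated correlation). In the fit without shNumb-ctr replicate 2, 2 HIN-200 genes were higher and 0 lower (camera adjusted p = 0.0022). The HIN-200 list was not tested without the genes called uncertain, Ifi204 among them, because too few members remained. Aim2, a cytosolic DNA sensor, went from 20.9 ± 0.599 to 24.5 ± 0.489 FPKM, and Ifi207 from 19.3 ± 0.447 to 22.5 ± 0.569 (SD, n = 3, log2 0.22 for both, limma adjusted p = 0.0072 and 0.0081). Interferon-stimulated genes as a list were not called (camera adjusted p = 0.0721, and adjusted p = 0.580 with an estimated correlation): Isg20, Rsad2, Oasl1 and Mx2 were higher and Oas2 and Dtx3l lower of 43 (1 and 0 adjusted over the list alone). Without shNumb-ctr replicate 2, 1 gene of that list was higher, with Mx2 below the filter and not tested. That list was called upward without shscr-ctr replicate 2 (camera adjusted p = 0.0033), and its camera adjusted p was 0.388 without shscr-ctr replicate 3. In cytosolic nucleic acid sensing, Ikbke rose and Sting1, Mavs, Trex1, Myd88 and Tlr7 fell, of 17 (2 and 5 adjusted over the list alone, camera adjusted p = 0.997, and adjusted p = 0.998 with an estimated correlation). Sting1, the adaptor downstream of the DNA sensor cGAS, fell from 32.4 ± 1.37 to 27.0 ± 1.38 FPKM (SD, n = 3, log2 -0.25, limma adjusted p = 0.0116). Of 16 inflammasome and pyroptosis genes, Aim2, Nlrp3, Ninj1 and Casp4 rose and Txnip and P2rx7 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.127, and adjusted p = 0.283 with an estimated correlation). Trex1 is uncertain, with 96.2% shared windows. Without shNumb-ctr replicate 2, 3 nucleic acid sensing genes and 1 inflammasome gene were lower. Of the called members of the interferon, nucleic acid sensing and inflammasome lists, only Isg20, Sting1, Aim2 and Nlrp3 kept the call in every alternative.

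Of 39 genes of G2/M and mitosis, 17 fell and 0 rose in the libraries labelled shNumb-ctr (25 and 0 adjusted over the list alone, camera adjusted p = 1.2e-07, and adjusted p = 0.269 with an estimated correlation). Of 44 genes of G1/S and DNA replication, 18 fell and 0 rose (24 and 0 adjusted over the list alone, camera adjusted p = 5.7e-07, and adjusted p = 0.269 with an estimated correlation). The median log2 fold changes were -0.15 and -0.14. Cdc20, which activates the anaphase-promoting complex, went from 59.8 ± 0.616 to 50.1 ± 1.16 FPKM, and Birc5 (survivin) from 52.1 ± 0.230 to 45.4 ± 1.00. Uhrf1 went from 50.5 ± 0.799 to 39.9 ± 0.354 and the replicative helicase subunit Mcm5 from 67.2 ± 3.01 to 53.03 ± 1.06 (SD, n = 3, log2 -0.25, -0.19, -0.33 and -0.33). Of 5 tested replication histone genes 1 was higher, H2bc4, itself uncertain with 29.7% shared windows (1 and 0 adjusted over the list alone). That list was called (camera adjusted p = 0.0126, and adjusted p = 0.198 with an estimated correlation), but not with no filter or after the GC and length correction.

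Of 12 heat shock genes 6 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 7.8e-04, and adjusted p = 0.269 with an estimated correlation), among them the chaperones Hsp90ab1, from 1407 ± 17.8 to 1263 ± 5.62 FPKM (SD, n = 3, log2 -0.16), and Hspa8 (log2 -0.26), which is uncertain with 52.4% shared windows. Of 26 targets of the stress transcription factor ATF4, 8 fell, and Atf3 and Ddit3 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0069, and adjusted p = 0.331 with an estimated correlation). Shmt2, of mitochondrial one-carbon metabolism, fell from 213 ± 5.38 to 180 ± 2.58 FPKM and Ddit4 from 35.8 ± 1.07 to 27.7 ± 1.07 (SD, n = 3, log2 -0.25 and -0.36). The call for Ddit3 was lost with no filter and without shscr-ctr replicate 2, shscr-ctr replicate 3 or shNumb-ctr replicate 1, with limma adjusted p up to 0.0630. Ribosomal protein genes had a median log2 fold change of 0.03, with 6 of 77 higher and 1, Rpl17, lower (2 and 1 adjusted over the list alone). Their upward call (camera adjusted p = 0.0066, and adjusted p = 0.424 with an estimated correlation) was lost without shNumb-ctr replicate 3, after quantile normalization and after the GC and length correction, with camera adjusted p up to 0.389.

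**Figure D3:**
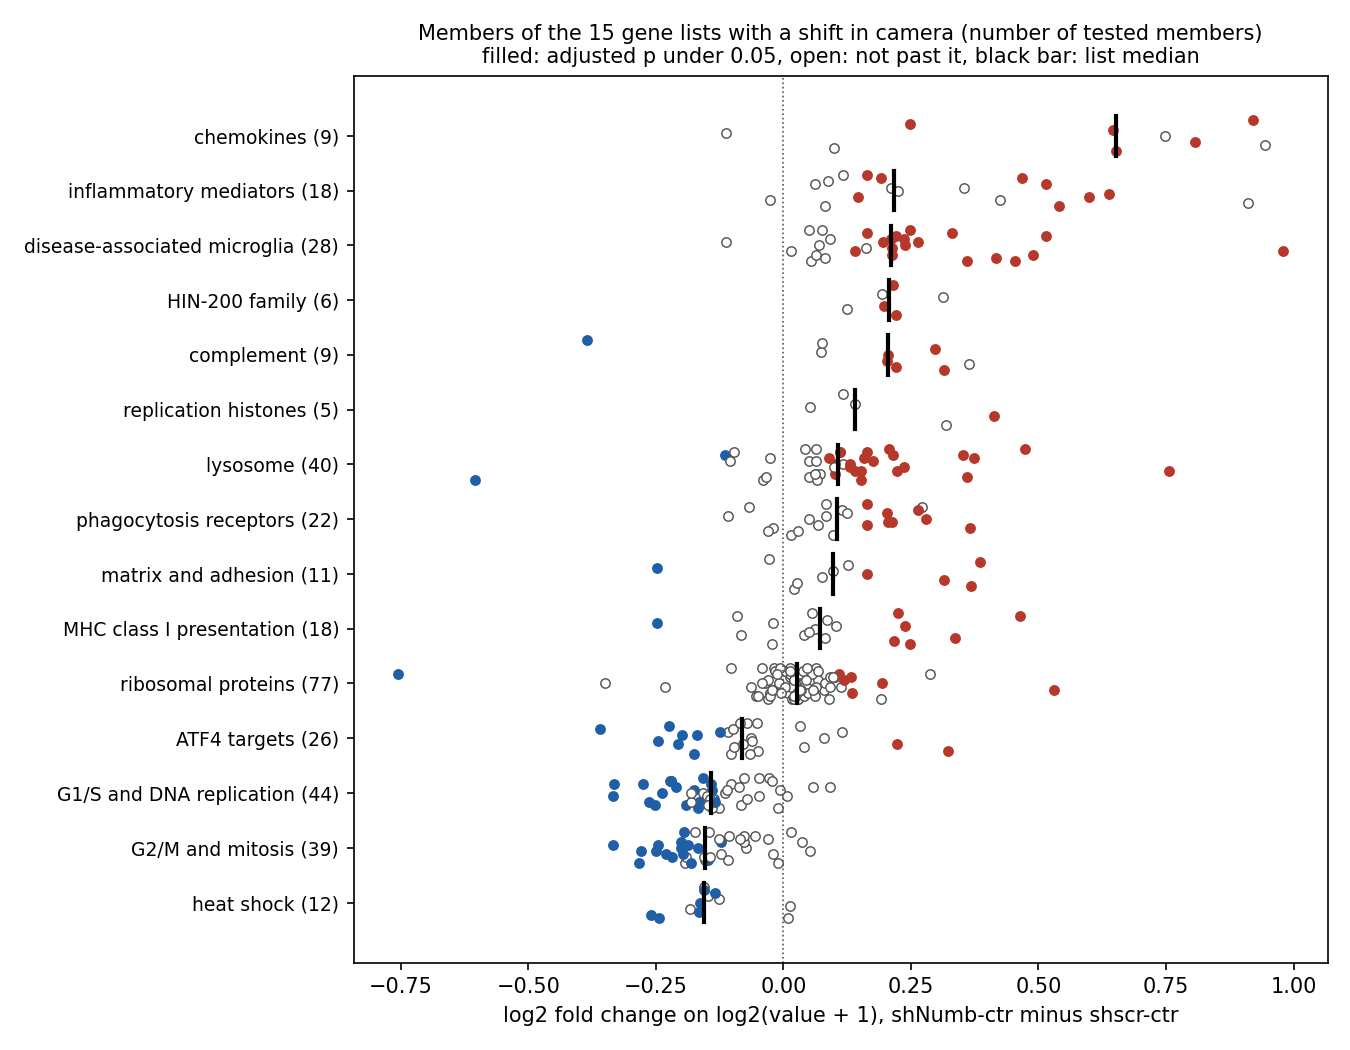
Log2 fold change (horizontal axis, libraries labelled shNumb-ctr minus shscr-ctr) of each tested member of the 15 lists called in camera, 1 line of points per list, with filled points past the threshold, open points not past it and a black bar at the list median. Chemokines have the highest median (0.65), disease-associated microglial genes lie at 0.21, and the medians of the G1/S, G2/M and heat shock lists are -0.14, -0.15 and -0.16.

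Numb restrains Notch signalling, and the Notch lists were examined for that reason. Numb RNA was not lower in the libraries labelled shNumb-ctr, so the changes in this paragraph cannot be taken as a readout of Numb loss. Notch1 fell from 2.01 ± 0.171 to 1.23 ± 0.0864 FPKM in the libraries labelled shNumb-ctr (SD, n = 3, log2 -0.43, SE 0.076, limma adjusted p = 0.0091). Of 31 pathway genes, Itch, Kat2a, Mfng and Notch2 also fell, and Dtx3, Rbpj and Numbl rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.143, and adjusted p = 0.283 with an estimated correlation). Dtx3 went from 34.5 ± 0.574 to 41.1 ± 0.267 FPKM (SD, n = 3, log2 0.25, limma adjusted p = 0.0021), and Rbpj, the DNA-binding partner of Notch, is uncertain with 24.3% shared windows (log2 0.21). Of 10 Notch target genes, Myc and Ccnd1 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0721, and adjusted p = 0.269 with an estimated correlation). Myc went from 0.591 ± 0.159 to 1.35 ± 0.170 FPKM (SD, n = 3, log2 0.56, limma adjusted p = 0.010). Myc passed the filter only through its shNumb-ctr values. Ccnd1 is uncertain, with 27.3% shared windows, and its call was lost in 8 of 15 alternatives, with limma adjusted p up to 0.106. Hes1 was listed at 0 in 4 of the 6 libraries and at 0.0306 and 0.0444 FPKM in the other 2. With shNumb-ctr replicate 2 left out, Myc fell below the filter and was not tested. In that fit 1 Notch target gene, Ccnd1, was higher (camera adjusted p = 0.144). Without shscr-ctr replicate 3 the target list was called upward (camera adjusted p = 0.0489). Numb is an endocytic adaptor, and of 31 genes of clathrin-mediated endocytosis, Dnm1, Dab2, Ehd4 and Rab11a rose and Itsn1, Eps15, Ap2a2 and Picalm fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.843, and adjusted p = 0.854 with an estimated correlation). Dab2, another clathrin adaptor, went from 96.9 ± 2.65 to 124 ± 5.13 FPKM (SD, n = 3, log2 0.35, limma adjusted p = 0.0015). Of 12 cell polarity genes, Scrib and Mark2 fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.260, and adjusted p = 0.498 with an estimated correlation). With the same library left out, 2 endocytosis genes and 1 polarity gene were lower. Of the members called in these lists, Notch1, Dtx3, Rbpj, Myc, Dnm1, Dab2, Itsn1 and Scrib kept the call wherever they were tested. The others lost it in at least 1 alternative.

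In MHC class I presentation 6 of 18 genes rose and Psmb10 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0019, and adjusted p = 0.198 with an estimated correlation), with B2m, the light chain of class I molecules, going from 835 ± 3.15 to 992 ± 26.4 FPKM (SD, n = 3, log2 0.25, limma adjusted p = 0.0015). In the list of matrix and adhesion genes Itga5, Itgb3, Lamc1 and Mmp12 rose and Itga4 fell, of 11 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0132, and adjusted p = 0.198 with an estimated correlation). The call of that list was lost with the filter at 5 FPKM (camera adjusted p = 0.109). The calls for Itgb3 and Lamc1 were lost without shscr-ctr replicate 1 (limma adjusted p = 0.0503 and 0.0527), that for Lamc1 also with the replicate number as a block (0.0550), and that for Mmp12 without shNumb-ctr replicate 3 (0.0507). With an estimated correlation 0 of the 38 lists were called in camera, 9 had an unadjusted p under 0.05, and the lowest adjusted p was 0.178; fry called 24.

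Lists that were not called held changed members too, and 1 such list is not described here. Hypoxia targets had 7 of 20 lower and 0 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.0540), led by Ddit4 and Kdm3a. Glycolysis had Eno1, Hk2, Pfkl, Slc2a1 and Pkm lower and 0 higher of 19 (5 and 0 adjusted over the list alone, camera adjusted p = 0.143). Eno1 and Pkm are uncertain with 72.2% and 34.7% shared windows, and Hk2, the inducible hexokinase, went from 25.1 ± 1.92 to 18.7 ± 0.166 FPKM (SD, n = 3, log2 -0.40, limma adjusted p = 0.0037). Immediate early genes went both ways, with Egr3, Myc, Atf3, Spry4 and Egr2 higher and Dusp1, Fos, Zfp36 and Jun lower of 26 (8 and 5 adjusted over the list alone, camera adjusted p = 0.331). Without shNumb-ctr replicate 2 the numbers were 2 and 6, with Myc and Egr2 below the filter and not tested. MHC class II presentation had Cd40, H2-Oa, Cd80 and Lgmn higher and Ifi30 lower of 10 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0734). Alternative activation had Igf1 higher and Il4ra, Mrc1 and Socs3 lower of 10 (2 and 3 adjusted over the list alone, camera adjusted p = 0.569). Mrc1, the mannose receptor, went from 1.84 ± 0.134 to 1.06 ± 0.188 FPKM (SD, n = 3, log2 -0.47, limma adjusted p = 0.0115). The unfolded protein response had Edem1, Hspa5, Sdf2l1 and Ern1 higher and Herpud1 and Canx lower of 20 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0721). Autophagy had Atg13, Gabarapl1 and Gabarapl2 higher and 0 lower of 24 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0721). Nrf2 targets had Me1, Hmox1 and Gpx4 higher and Pgd, Tkt, Gclc and Osgin1 lower of 23 (3 and 4 adjusted over the list alone, camera adjusted p = 0.292; Me1 and Gpx4 are uncertain, with 32.3% and 61.0% shared windows). For p53 targets, the list had Plk2, Rrm2b and Plk3 higher and Trp53 and Ephx1 lower of 25 (3 and 2 adjusted over the list alone, camera adjusted p = 0.162). Cholesterol synthesis had Msmo1 higher and Dhcr7 and Stard4 lower of 21 (1 and 2 adjusted over the list alone, camera adjusted p = 0.395). LXR targets had Npc2 and Mylip higher and Scd2, Srebf1 and Lpcat3 lower of 14 (2 and 3 adjusted over the list alone, camera adjusted p = 0.807). Wnt targets had Myc and Ccnd1, the same genes as in the Notch target list, higher of 6 (3 and 1 adjusted over the list alone, camera adjusted p = 0.102). Nuclear genes of oxidative phosphorylation had Cyc1 and Atp5f1b lower of 44. The mitochondrially encoded genes had mt-Nd2 lower of 13 (0 and 0 adjusted over the list alone for both, camera adjusted p = 0.676 and 0.757). Without shNumb-ctr replicate 2, 18 lists were called in place of 15, among them hypoxia and MHC class II (camera adjusted p = 0.0436 and 0.0378) and the list not described here. The hypoxia list was also called downward without shscr-ctr replicate 3 or shNumb-ctr replicate 1 (camera adjusted p = 0.0377 and 0.0215), with no filter and with the filter at 5 FPKM (0.0333 and 0.0401). MHC class II was also called upward without shscr-ctr replicate 1 (camera adjusted p = 0.0439), with the filter at 5 FPKM (0.0401) and without genes with shared windows (0.0413). Autophagy was called upward without shNumb-ctr replicate 3, after quantile normalization and without genes with shared windows (camera adjusted p = 0.0490, 0.0499 and 0.0402). The unfolded protein response was called upward after median-of-ratios rescaling and quantile normalization (camera adjusted p = 0.0442 and 0.0402), and glycolysis downward after quantile normalization (0.0142). With shNumb-ctr replicate 2 left out, 1 autophagy gene and 1 Nrf2 target were higher, and 1 gene each of the unfolded protein response and the p53 targets was lower. With that library left out, 0 cholesterol synthesis genes were higher and 1 lower, 3 LXR targets were higher and 2 lower, 1 nuclear oxidative phosphorylation gene was higher and 0 lower, and 0 mitochondrially encoded genes passed (limma). Of the 107 called genes counted in lists that were not called, the list not described here included, 43 kept the call in every alternative in which they were tested and 64 lost it in at least 1, with the highest limma adjusted p of these 64 between 0.0508 and 0.188. Among the 64 are Slc2a1, Pkm, Spry4, Egr2, Zfp36, Jun, Lgmn, Ifi30, Socs3, Ern1, Herpud1, Canx, Gabarapl1, Gabarapl2, Hmox1 and Gpx4. So are Tkt, Gclc, Osgin1, Rrm2b, Plk3, Ephx1, Msmo1, Stard4, Mylip, Lpcat3, Ccnd1, Cyc1, Atp5f1b and mt-Nd2. Those that kept the call in all 16 alternatives include Kdm3a, Hk2, Irak2, Sting1, Dtx3, Dab2, Edem1 and Plk2. Mrc1 and Notch1 were tested in 15 and Myc in 12, since Myc fell below the filter at 5 FPKM and whenever a shNumb-ctr library was left out.

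The median and the test of a list differed in sign for TLR4 and NF-kB signalling (median log2 -0.003, mean 0.02, camera upward), for clathrin-mediated endocytosis (median -0.03, mean 0.01, camera upward) and for nuclear oxidative phosphorylation genes (median -0.003, mean 0.01, camera upward, fry downward). For alternative activation (median 0.07, mean 0.01) camera pointed upward and fry downward. None of these 4 lists was called in camera.

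Markers of other cell types and the hedgehog pathway were not tested as lists, because fewer than 5 members of each passed the filter. With no filter, all but the fibroblast markers were tested, and their camera adjusted p were 0.152 to 0.976. The markers of fibroblasts summed to at most 0.191 FPKM in any library, and those of epithelial cells to 1.17 FPKM in shNumb-ctr replicate 2 and at most 0.092 in each of the other 5. Neuronal markers summed to 4.19 to 4.63 FPKM in the libraries labelled shscr-ctr and 4.98 to 5.14 in those labelled shNumb-ctr, and endothelial markers to 27.6 to 29.2 and 32.7 to 34.1. Lymphocyte markers summed to 2.92 to 3.52 and 2.29 to 2.50 FPKM, oligodendrocyte markers to 16.7 to 18.1 and 17.0 to 17.4, and hedgehog genes to 22.3 to 24.4 and 20.9 to 22.1. As single genes, the endothelial markers Vwf and Flt1 were called higher and the lymphocyte marker Lck lower. Vwf kept its call in all 16 alternatives, while Flt1 lost it in 8 of 16 and Lck in 1 of 15. Astrocyte markers summed to 62.8 to 66.0 and 64.8 to 69.0 FPKM, almost all of it Aldoc, a glycolytic enzyme that the glycolysis list also holds, at 64.3 ± 1.58 and 67.3 ± 2.31 FPKM (SD, n = 3).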

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

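The rescaling by median of ratios, quantile normalization, the GC and length correction, the constant prior variance, leaving out genes with shared windows, and the lists without shNumb-ctr replicate 2 were chosen after the result was seen. Numb stayed positive and short of the threshold in each alternative run (limma adjusted p 0.0875 to 0.324). Of the values of single named genes over the alternatives, 2637 kept direction and side of the threshold, 478 kept the direction and lost the threshold, and 6 reversed. With the replicate number as a block, 520 genes were higher and 559 lower, and Ifi204 (log2 0.20) had an adjusted p of 0.0529. In that fit the interferon-stimulated and Notch target lists were called (camera adjusted p = 0.0364 and 0.0499). The replicate numbers did not pair the samples (correlations of same-number deviations 0.0067, 0.012 and 0.047). A fold of at least 1.5 left 53 higher and 14 lower genes. Camera with an estimated correlation called 0 lists and fry 24. With 1 library left out, 499 to 671 genes were higher and 465 to 869 lower, 15 to 18 lists were called, and the log2 fold change of Ifi204 was 0.17 to 0.24 (adjusted p 0.0191 to 0.0869). Fewer samples lower the power of such fits. Tnf reversed to 0.0079 without shscr-ctr replicate 3 and to 0.15 without shNumb-ctr replicate 1, in a range of -0.14 to 0.15 over the libraries left out. Without shNumb-ctr replicate 2, which held their highest values, Ptgs2, Il1a and Saa3 reversed to -0.019, -0.020 and -0.043, the low ends of ranges that reached 0.22, 0.65 and 0.56. None of these 4 genes passed the threshold in those fits. Fth1 went to -1.6e-15 under quantile normalization, which gives top-ranked genes the same value in each library. The alternatives that need counts were not run. Depth is unknown, so which low values it limits is not known either.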

Other observations

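The 8 gene lists, the genes and the tests in this part were chosen only after the result was seen, except the splits of the libraries and the comparison of genes with and without shared sequence. Genes of ribosome biogenesis were lower in the libraries labelled shNumb-ctr, with 20 of 28 lower and 0 higher and a median log2 fold change of -0.19 (camera adjusted p = 2.2e-10, and adjusted p = 0.0928 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, went from 27.8 ± 1.19 to 21.97 ± 0.538 FPKM and Ddx21 from 56.3 ± 2.43 to 44.6 ± 1.74 (SD, n = 3, log2 -0.33 for both, limma adjusted p = 0.0027 and 0.0029). Of 17 cytosolic tRNA synthetase genes 9 were lower and 0 higher, among them Tars1 and Gars1 (camera adjusted p = 2.0e-04, and adjusted p = 0.0928 with an estimated correlation). Of 8 genes of the CCT chaperonin 5 were lower, led by Cct3 and Cct8 (camera adjusted p = 7.6e-04, and adjusted p = 0.196 with an estimated correlation). The proteasome core (1 higher and 3 lower of 25) and the circadian clock (0 and 2 of 14) were not called (camera adjusted p = 0.0645 and 0.411, and adjusted p = 0.502 with an estimated correlation for both). Without shNumb-ctr replicate 2 the proteasome core was called downward with the preset correlation (camera adjusted p = 0.0182), and an estimated correlation was not run in that setting.

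Genes shared with osteoclasts, the bone-resorbing relatives of macrophages, went both ways in the libraries labelled shNumb-ctr. Of 12, Spp1, Atp6v0d2, Gpnmb, Ctsk, Mmp9 and Itgb3 rose, Ocstamp fell and 5 did not pass (camera adjusted p = 2.2e-04, and adjusted p = 0.104 with an estimated correlation). Spp1 and Atp6v0d2 were already known to be among the largest rises when the list was chosen, so its p-value is not separate support. In a list of 13 genes of the vacuolar proton pump, which does not hold Atp6v0d2, 5 were higher and 0 lower. Atp6v1d and Atp6v1g1 led that list (camera adjusted p = 9.8e-04, and adjusted p = 0.0928 with an estimated correlation). In iron handling, the ferritin genes Fth1 and Ftl1, the exporter gene Slc40a1 and Hmox1 rose and the transferrin receptor gene Tfrc fell, of 10 (camera adjusted p = 0.0208, and adjusted p = 0.104 with an estimated correlation). The call for Hmox1 was lost in 8 of 16 alternatives, among them each library left out but shscr-ctr replicate 1, with limma adjusted p of 0.0713 and 0.105 without shscr-ctr replicates 2 and 3, and 0.0554, 0.102 and 0.0925 without shNumb-ctr replicates 1, 2 and 3. Fth1 went from 4081 ± 72.5 to 5727 ± 204 FPKM (SD, n = 3, log2 0.49), and to a log2 fold change of -1.6e-15 under quantile normalization; Ftl1 is uncertain with 91.3% shared windows and lost its call there (limma adjusted p = 0.111). Among single genes, Cyp11a1, the cholesterol side-chain cleavage enzyme, went from 0.628 ± 0.146 to 7.32 ± 0.575 FPKM (SD, n = 3, 11.6-fold, limma adjusted p = 1.9e-05), Lipg, endothelial lipase, from 0.942 ± 0.131 to 4.73 ± 0.0132 and Cxcr2 from 5.67 ± 0.418 to 2.61 ± 0.213 (log2 1.56 and -0.89). Cyp11a1 passed the filter only through its shNumb-ctr values, so it was not tested when a shNumb-ctr library was left out. Its fold rests on shscr-ctr values below the filter.

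The real grouping gave 1989 genes past the threshold, and the highest of the other 9 splits of the 6 libraries into 3 and 3 gave 5. Only 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

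Numb was not lower in the libraries labelled shNumb-ctr. An effective knockdown with exchanged group labels would give a fold well above the 1.06 found, and 1 wrong label among effective knockdowns would give more than the 1.118-fold between the highest and lowest library. Reads of a copy are argued against by the 0.86% of Numb windows found in other genes. A hairpin that acts on translation, a hairpin without effect on Numb, and a difference in growth or handling between the groups stay open, since protein was not measured here and no label names a batch.

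The genes Csf3, Cxcl2, Lcn2, Il6, Il1b, Cxcl10, Saa3, Il1a and Ccl7 were high in shNumb-ctr replicate 2 alone, with Csf3 at 11.7 FPKM against at most 1.05 elsewhere. Other genes were high there too, such as Tpd52 at 37.9 FPKM against at most 24.9 elsewhere. That library also held 306 genes above 0 in no other library, against 130 to 168 for each of the others, with depth unknown. The values argue against fibroblast RNA (marker sum 0.191, at most 0.125 elsewhere) and against an acute stimulation of the whole culture (median log2 difference of 10 NF-kB feedback targets 0.085, highest 0.40 for Bcl3). RNA of epithelial cells may contribute and stays open (marker sum 1.17, at most 0.092 elsewhere; Krt8 0.342 FPKM), as does a late or partial stimulation, which was not tested. Of 16 genes high in that library, 9 had their highest shscr-ctr value in replicate 3, but many of these genes respond together and others lie near 0, so the count decides nothing about the same material there.

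Gapdh varied 5.76-fold between libraries (186, 158 and 36.3 FPKM in shscr-ctr, 58.9, 176 and 32.3 in shNumb-ctr), the rank 15 spread within groups of 8247 genes. The median spread within groups was 1.19 times as large in 1320 genes with over 20% shared windows as in genes of like level among 5088 with none. A permutation test of the mean log2 spread, not of that median ratio, gave p = 1e-05, the smallest that 100000 permutations can give. Of the 82 most discordant genes with a known value, 34 had over 20% shared windows (41.5%, against 12.5% of genes at large), and Gapdh has 27.2%. Assignment of reads among copies may therefore contribute to such spread, and stays open because the authors' aligner and annotation are not known. No biological explanation was tested.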
